A study of Mus musculus with 4 samples.

How the data were processed

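The series measured RNA in explant cultures of mouse dorsal root ganglia, the clusters of sensory neurons and their glia beside the spinal cord. Per the labels, ganglia of C57BL/6 embryos at embryonic day 13 were kept in growth medium until day in vitro (DIV) 8 and then in myelination medium. ES cultures received electrical stimulation (20 Hz, 50 mV/mm, 1 h) at 10 DIV and control cultures received none. RNA was harvested at 11 or 19 DIV, and the RNA of 3 explants was pooled per condition. The 4 libraries (control and ES at 11 DIV, control and ES at 19 DIV) were therefore 1 library per group, with no replicates. Libraries were made from 500 ng of total RNA with a QuantSeq kit, per the labels' protocols, which reads tags at the 3' ends of transcripts. The submitters' processing notes name Bowtie2, bedtools and the mouse build mm10. Versions, the handling of duplicate reads and the use of strand in counting are not given in the sources used here, so overlapping and antisense genes could not be told apart.

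The deposited values are raw read counts per gene symbol, 1 table per library, in whole numbers, and the authors' tables had the same 23282 rows in the same order. The totals were 6197537 reads in control and 5782834 in ES at 11 DIV, and 6730614 in control and 7830950 in ES at 19 DIV. All rows named a gene. Of the symbols, 35 stood on more than 1 row (79 rows), and these rows were kept apart. No row was mitochondrially encoded. In 812 pairs of rows, made of 517 rows, the counts lay within 5% of each other in every library. Of these pairs, 703 had reads in 1 library only, where similar counts need not come from shared reads, and 38 had reads in all 4. Values of the 38, such as Gstp1 and Gstp2, are uncertain, since reads counted for 2 genes at once would look the same. Gene positions were taken from GENCODE M21 on GRCm38, the same assembly as mm10, in which 22159 of the 23238 distinct symbols occurred once.

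Counts were scaled by effective library size with TMM (edgeR 4.0.16 in R 4.3.3) over the 4 libraries and given as CPM. For each of the 4 comparisons of 2 libraries, the fold was the ratio of CPM with an exact Clopper-Pearson 95% interval on the 2 counts. The size rule asked for at least 2-fold, an interval excluding equality and at least 50 reads in the higher library. These intervals compare libraries, not conditions, and cover counting error only. Log2 differences used a prior count of 2. For gene lists, 40 lists of pathway and cell type genes had been fixed. A list's median log2 difference over members with a mean of at least 10 reads was placed among the medians of 10000 random lists of the same size, matched on mean reads in 20 bins. A list was said to stand apart below the 2.5th or above the 97.5th percentile. About 5% of lists of independent genes do so by chance. Genes within a list are not independent, so the share for these lists can differ. At least 3 members were measured in 38 lists. Across all 4 libraries, edgeR's quasi-likelihood test was fitted with ES and day as additive factors (1 residual degree of freedom, filterByExpr, Benjamini-Hochberg threshold 0.05). DESeq2 1.42.0, limma 3.58.1 with voom, other scalings, count minimums, fold minimums, thinning to the smallest total and other list settings were the alternatives. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

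The named genes were, per comparison, the 8 genes furthest above and the 8 furthest below equality by the nearer end of the counting interval. To these came, per list described, the 2 most abundant members and up to 2 members with the largest difference past the size rule, and Egr2, Mbp, Pmp22, Prx, Mag, Fos, Egr1, Atf3, Gap43, Sox10, Ngfr and Jun. Some genes that the rule names are not reported here. For the model over 4 libraries the rule took up to 10 genes per direction past the threshold. The design, the lists, the alternatives and this rule were set before the data were examined.

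The counts were clumped. In 2602 rows 1 library had 0 reads and another more than 200. Separately counted molecules would not give this for a gene at the same level in both, although a real difference could. Taking the share of 0 counts among genes expected at 200 to 1000 reads as Poisson, 1 sampled molecule stood for 112 to 154 reads, depending on the library, or 49296 to 55583 molecules per library. The expected reads came from the other libraries, and every 0 was taken as sampling. Real differences between libraries would therefore raise the estimated reads per molecule. An interval that allows for this was added after seeing the data. Counts were divided by a spread factor, the median squared difference between the 2 libraries relative to counting error over genes with a mean of 500 to 3000 reads, which was 208 to 258. The spread-adjusted rule kept the 2-fold and 50-read limits and asked that a 99% interval on the divided counts exclude equality. Printed spread-adjusted intervals are at 95%. Genes past this rule, up to the 20 furthest per direction, were named as well. A first version with a 99.9% level and genes of 200 to 2000 mean reads was replaced after it had recovered few changed genes in simulated libraries and before its counts in the real libraries were seen. Because the spread factor holds any real differences between the 2 libraries too, these intervals describe how far a gene stands out from other genes and are not replicate errors. The factor was not estimated for genes above 3000 mean reads, such as Mt1, Mt2 and Rn45s. Their intervals assume the same factor and may be too narrow.

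The rules for genes and lists were tested on simulated data for ES against control at 11 DIV only, and the model over 4 libraries for both factors. For ES against control at 11 DIV, 2 clumped libraries of 23282 rows with no changed gene gave 5542 genes past the size rule and 3 past the spread-adjusted rule. With 200 genes of at least 500 mean reads changed, the spread-adjusted rule recovered 3.5% of those changed 2-fold, 22.5% at 4-fold and 50.5% at 8-fold. Its first version recovered 1%, 11.5% and 39.5%. The spread factor of the rule in these runs was 279 to 298, above the 208 of the real pair. The recovered shares may therefore not hold for the real pair. In the model over 4 libraries, simulated with 200 genes changed by ES, 1% were recovered at 2-fold with 1 false call among 9030 tested, and 40% at 4-fold with 2 false calls among 8996. With 200 genes changed by day, 1% were recovered at 2-fold with 0 false calls among 8977, and 46% at 4-fold with 4 among 9041. For lists of 20 genes in 2 clumped libraries, simulated for ES against control at 11 DIV, 3.5% of 200 lists stood apart with no changed gene among 9339. Of 10 lists with all members changed, 3 stood apart at 1.5-fold, 6 at 2-fold and 10 at 4-fold, and so did 4.5%, 3.5% and 7.5% of 200 unchanged lists in these runs. Members of the simulated lists were drawn at random and varied independently. These shares therefore do not cover lists whose genes vary together.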

Results

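RNA was counted in 4 libraries of cultured mouse dorsal root ganglion explants, 1 for each combination of treatment (electrical stimulation, ES, or none) and harvest day (11 or 19 days in vitro, DIV). Each library pooled 3 explants, and there were no replicates, so no difference below has a replicate check and the intervals describe the libraries that were compared. Total counts ranged from 5782834 to 7830950 reads, and 9632 to 9996 of the 23282 gene rows had a read. At these totals 3 reads, the limit that a count of 0 allows if reads are independent, corresponded to 0.376 to 0.518 CPM after TMM scaling. With 1 sampled molecule estimated to stand for 112 to 154 reads, the reads here were not independent. Folds given below as at least a value put 0 at 3 reads and are not lower limits once clumping is allowed for. Across the 9759 genes with a mean of at least 50 reads, the log2 CPM values of any 2 libraries correlated with Pearson r between 0.458 and 0.538. Across the 564 genes with a mean of at least 2000 reads r lay between 0.588 and 0.781. Genes are not independent replicates, and these correlations describe how far low-count values scattered between libraries. Rn45s, the ribosomal RNA precursor, took 5.18% of the reads in control at 11 DIV, against 3.08% in ES at 11 DIV, 2.82% in control at 19 DIV and 2.65% in ES at 19 DIV.

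The series was made to study effects of electrical stimulation, and the first comparison set ES against control at 11 DIV, 1 day after stimulation. Genes of compact and non-compact myelin were higher in the ES library. The median log2 difference of the 24 measured members was 1.35, at the 100th percentile of matched random lists. By the size rule 14 members were higher, 2 lower and 8 neither. The same rule called 2845 genes higher and 2913 lower among the 9834 with at least 50 reads. Such counts of list members, here and below, are to be read against shares of this size. The spread-adjusted rule, added after seeing the data, called 1 member of the list higher and 0 lower. Pmp22, a membrane protein of compact myelin (a protein-coding gene on chromosome 11, positions 63128982 to 63159547 in GRCm38), had 2926 reads in ES and 1839 in control. It was 1.56-fold higher, with a spread-adjusted interval of 0.625 to 4.10. Mbp, myelin basic protein, was 1.39-fold (0.791 to 2.47), Prx 2.48-fold (0.495 to 19.0) and Mag 3.70-fold (0.441 to 107) higher, and the intervals of all 4 genes included equality. Cldn19, a tight junction protein, and Fa2h, a hydroxylase of myelin lipids, had 374 and 360 reads in ES and 0 in control, at least 122-fold and 117-fold higher than a count of 3. Neither passed the spread-adjusted rule. Egr2, a transcription factor that Schwann cells need to myelinate, had 585 reads in ES and 3 in control, a ratio of 191 with a counting interval of 64.9 to 927 but a spread-adjusted lower end of 0.357. Sox10 and Ngfr, which Schwann cells express before they myelinate too, were at 0.869 (0.433 to 1.73) and 0.951 (0.430 to 2.10) times control. The Schwann lineage list, which shares members with the myelin list, had a median of 0.35 over 17 members and did not stand apart (percentile 94.3). It stood higher with members of at least 50 mean reads (0.47, percentile 97.66) and of at least 500 (0.59, percentile 98.34), a minimum added after seeing the data.

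**Figure D1:**
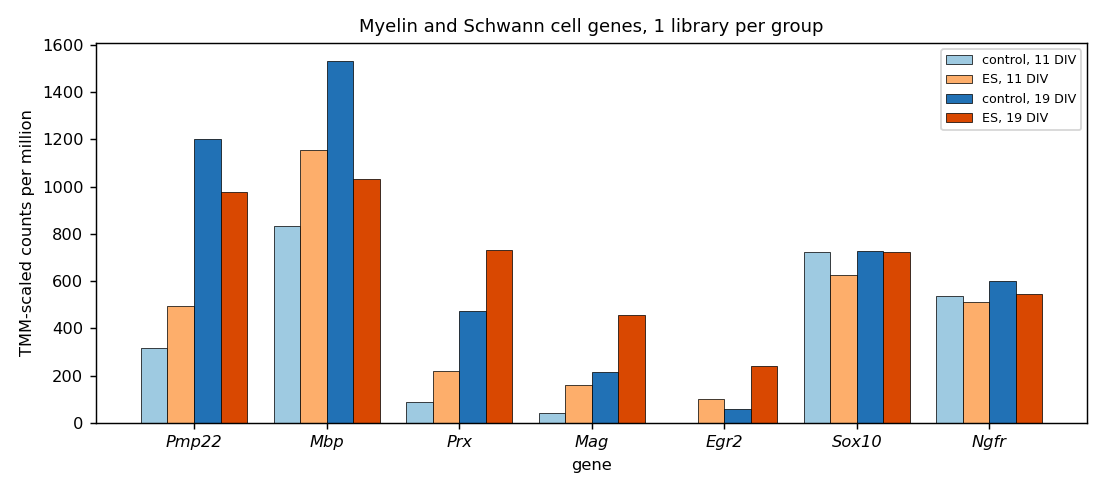
TMM-scaled CPM (vertical axis, from 0) of 7 myelin and Schwann cell genes, with 1 bar per library and no error bars because each group had 1 library. Pmp22 stood at 317 CPM in control at 11 DIV, 494 in ES at 11 DIV, 1201 in control at 19 DIV and 979 in ES at 19 DIV.

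Of the neuronal lists, 2 stood higher in the ES library at 11 DIV. Synaptic vesicle and exocytosis genes had a median log2 difference of 1.57 over 27 members (16 higher, 2 lower and 9 neither by the size rule), at the 100th percentile. Pan-neuronal markers had a median of 0.84 over 23 members (9 higher, 2 lower, 12 neither), at percentile 99.98. The spread-adjusted rule called 1 member of each of these lists higher and 0 lower. Nociceptor markers (median 0.83, percentile 96.86), regeneration-associated genes (0.51, 97.22), ion channels (0.49, 90.93) and markers of mechanoreceptors and proprioceptors (0.02, 57.5) did not stand apart. Tac1, the precursor of substance P (protein-coding, chromosome 6, 7554879 to 7565834), was 2.82-fold higher (1.58 to 5.29), while Calca, the precursor of calcitonin gene-related peptide, was at 0.547 times control (0.241 to 1.18). Prph and Stmn2, a neurofilament protein and a microtubule regulator of neurons, were 1.79-fold (0.986 to 3.33) and 1.37-fold (0.704 to 2.70) higher. Sncg, a synuclein of sensory neurons, was 4.78-fold (1.43 to 23.2) and Nrxn2, a neurexin outside these lists, 11.0-fold (1.87 to 284) higher. Axon-glia contact genes (median 0.73, percentile 99.01), fatty acid synthesis genes (0.74, 99.59), basal lamina genes (0.49, 99.25) and nuclear oxidative phosphorylation genes (0.22, 98.65) stood apart on the same side. Scd2, a fatty acid desaturase, was 1.57-fold higher (0.95 to 2.65), and Sparc, an abundant member of the basal lamina list, 1.24-fold (1.0 to 1.54).

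The oxidative stress response genes were lower in the ES library at 11 DIV, with a median log2 difference of -1.43 over 20 members, below all 10000 random lists (percentile 0). By the size rule 14 members were lower, 0 higher and 6 neither, and by the spread-adjusted rule 4 were lower and 0 higher. The metallothioneins Mt1 (chromosome 8, 94179082 to 94180327) and Mt2 (chromosome 8, 94172664 to 94173568), protein-coding genes whose products bind metal ions, had 6441 and 6878 reads in ES and 48987 and 54127 in control, or 0.129 (0.0854 to 0.188) and 0.124 (0.0838 to 0.179) times control. Prdx1, a peroxidase, was at 0.333 times control (0.244 to 0.447) and Hmox1, heme oxygenase, at 0.173 (0.0397 to 0.536). The ferritin chains Fth1 and Ftl1, outside the list, were at 0.480 (0.325 to 0.699) and 0.457 (0.291 to 0.703). Gclc, an enzyme of glutathione synthesis, had 6 reads in ES and 1449 in control. In the same libraries Rn45s took 3.08% of the reads in ES and 5.18% in control. Ribosomal protein genes were lower as well, with a median of -0.42 over 83 members (percentile 0.11), although 78 of them were neither higher nor lower by the size rule. Rps20 and Rps9 were at 0.719 (0.492 to 1.05) and 0.689 (0.447 to 1.05) times control. The apoptosis and p53 response list had a median of -0.76 over 20 members (percentile 1.53), with Cdkn1a, a cell cycle inhibitor, at 0.453 times control (0.256 to 0.776) and Mdm2 at 0.730 (0.284 to 1.81). Macrophage markers (median -4.01 over 14 members, or -3.73 with members at 0 reads put at a count of 3; percentile 0.71) and perineurial markers (-2.35 over 10, or -2.14; percentile 0.70) were low-count lists. The most abundant macrophage markers, Laptm5 and Csf1r, had 199 and 189 reads in ES and 188 and 0 in control. With only members of at least 500 mean reads, a minimum added after seeing the data, the p53 list (median -0.61 over 11, percentile 6.37) and perineurial markers (0.82 over 3, percentile 84.47) no longer stood apart and fewer than 3 macrophage markers were left. Against unmatched random lists the axon-glia, fatty acid, basal lamina, oxidative phosphorylation and p53 lists did not stand apart, nor with members of at least 50 mean reads did the macrophage (median -1.35) and oxidative phosphorylation (0.21) lists.

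**Figure D2:**
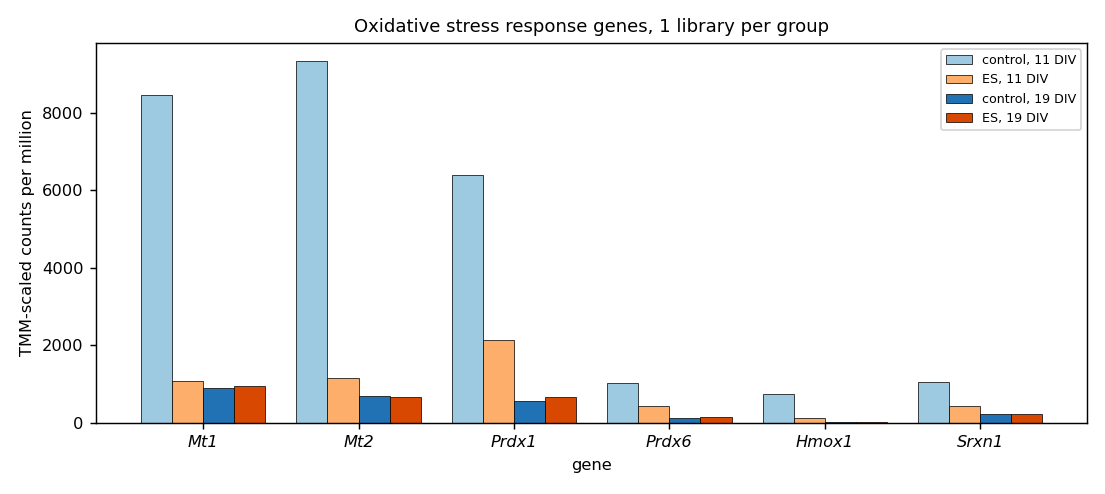
TMM-scaled CPM (vertical axis, from 0) of 6 oxidative stress response genes, 1 bar per library with no error bars. Mt1 stood at 8456 CPM in control at 11 DIV, against 1087 in ES at 11 DIV, 900 in control at 19 DIV and 945 in ES at 19 DIV.

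Immediate early and activity-regulated genes, which neurons switch on with activity, did not stand apart 1 day after stimulation (median 0.03 over 30 members, percentile 62.08; 10 higher, 7 lower, 13 neither). Fos had 184 reads in ES and 21 in control, Egr1 908 and 824, and Jun 1786 and 875. Atf3 had 0 and 224 (at least 76.4-fold lower with 0 put at a count of 3) and did not pass the spread-adjusted rule. Jund and Ier3, the most abundant members, were at 1.45 (0.442 to 5.16) and 0.414 (0.134 to 1.12) times control, and Gap43, a growth cone protein of the pan-neuronal and regeneration lists, at 1.90 (0.701 to 5.73). By the size rule 2845 genes were higher and 2913 lower among 9834 with at least 50 reads, and 1958 of these calls had 0 reads in 1 library. Simulated clumped libraries with no changed gene gave 5542 such calls, although their spread factor of 270 was above the 208 of the real pair. How many calls clumping alone would give is therefore uncertain, and these counts carried little information on their own. The spread-adjusted rule, added after seeing the data, gave 10 genes higher and 21 lower. Among the 10 higher were Tac1, Nrxn2, Sncg, Itih5, Aatk, Ngfrap1, Tcf25, Col4a1 and Apoe. Among the 21 lower were Mt1, Mt2, Prdx1, Hmox1, Fth1, Ftl1, Cdkn1a, the glutathione transferase rows Gstp1 and Gstp2 (whose counts lay within 5% of each other in every library), Slc3a2, Pgd, Pkm and Hmga2. The genes furthest apart by counting error alone all had 0 reads in 1 library. Brsk2, Dab1, Col15a1, Pfdn6, Anks1b, Rab3gap2, Megf9 and Fry had 742 to 1374 reads in ES, at least 242-fold to at least 448-fold higher than a count of 3 in control, and Fbxo28, Plekhm2, Chid1, Brd9, Slc12a4, 2810004N23Rik, 9430020K01Rik and Surf6 had 736 to 1010 reads in control and 0 in ES, at least 251-fold to at least 344-fold lower. None of these 16 passed the spread-adjusted rule, nor did any other gene with 0 reads in 1 library.

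**Figure D3:**
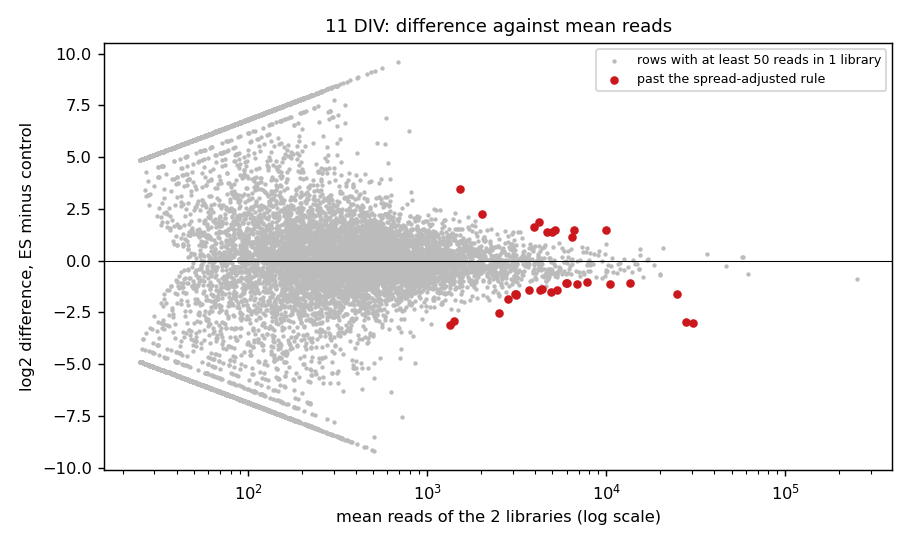
Log2 difference between ES and control at 11 DIV (vertical axis) against the mean reads of the 2 libraries (horizontal axis, log scale) for the 9834 gene rows with at least 50 reads in 1 library. The 31 genes past the spread-adjusted rule are in red, and the scatter of the rest widened toward low reads, where straight lines hold genes with 0 reads in 1 library.

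The comparison of ES with control at 19 DIV, 9 days after stimulation, had neuronal genes lower in the ES library. Pan-neuronal markers had a median log2 difference of -1.41 over 23 members (0 higher, 14 lower, 9 neither), below all 10000 random lists (percentile 0). Synaptic vesicle genes had a median of -1.40 over 27 members (1 higher, 15 lower, 11 neither; percentile 0.06), nociceptor markers -1.59 over 15 (3, 7 and 5; percentile 0.41) and ion channels -1.17 over 25 (4, 14 and 7; percentile 1.62). By the spread-adjusted rule 3 pan-neuronal and 2 nociceptor members were lower and 0 higher. No synaptic vesicle gene or ion channel of these lists passed that rule. Regeneration-associated genes (median -0.63, percentile 0.96) and fatty acid synthesis genes (-0.54, percentile 1.46) were also lower. Prph (protein-coding, chromosome 15, 99055174 to 99058978) had 2717 reads in ES and 6242 in control, or 0.376 times control (0.171 to 0.775). Stmn2 was at 0.332 (0.135 to 0.746), Tac1 at 0.272 (0.122 to 0.558) and Calca at 0.331 (0.148 to 0.688) times control. Tubb3, the neuronal beta-tubulin, was at 0.316 (0.113 to 0.777). Outside these lists, Map1b, a microtubule-associated protein, was at 0.467 (0.277 to 0.770), and Nrxn2 had 12 reads against 2336. Gap43 was at 0.479 times control (0.136 to 1.5). Markers of mechanoreceptors and proprioceptors had a median of -0.43 and did not stand apart (percentile 16.84). Hypoxia and glycolysis genes had a median of -0.45 (percentile 3.03) and stood lower with members of at least 50 (-0.49, percentile 1.83) and 500 mean reads (-0.55, percentile 0.8).

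**Figure D4:**
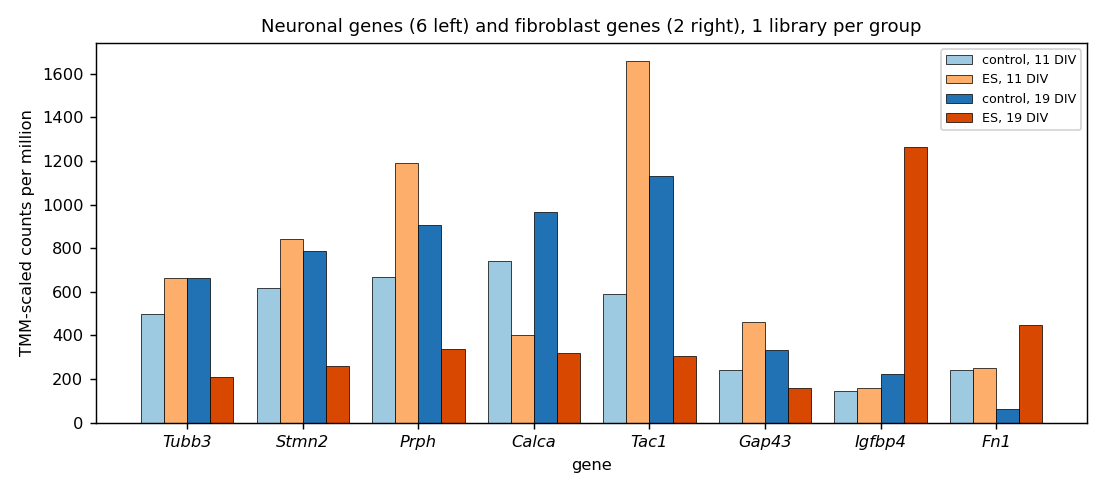
TMM-scaled CPM (vertical axis, from 0) of 6 neuronal genes and 2 fibroblast genes, 1 bar per library with no error bars. Tac1 stood at 1659 CPM in ES at 11 DIV and 308 in ES at 19 DIV, and Igfbp4 at 1262 in ES at 19 DIV against 221 in control at 19 DIV.

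Fibroblast and collagen genes were higher in the ES library at 19 DIV, with a median log2 difference of 0.75 over 24 members (8 higher, 0 lower, 16 neither; percentile 99.96). By the spread-adjusted rule 2 members were higher and 0 lower. Col1a1 and Col1a2, the chains of type I collagen, were 1.49-fold (1.11 to 2.02) and 1.24-fold (0.995 to 1.54) higher. Igfbp4, a binding protein of insulin-like growth factors (protein-coding, chromosome 11, 99041244 to 99054392), was 5.71-fold higher (2.48 to 15.7) and Fn1, fibronectin, 6.94-fold (1.58 to 67.5). Other genes past the spread-adjusted rule were Igfbp7 (2.63-fold, 1.47 to 4.98), Igfbp5 (2.29-fold, 1.38 to 3.93), Spp1 (2.78-fold, 1.40 to 5.94), Apod, Ahnak and Rcn1. The apoptosis and p53 response list was higher (median 1.10 over 20 members, 11 higher, 0 lower, 9 neither; percentile 99.91), but its abundant members Cdkn1a and Mdm2 were at 1.08 (0.501 to 2.36) and 0.957 (0.325 to 2.86) times control. Btg2, of the same list, had 1249 reads in ES and 0 in control (at least 359-fold higher than a count of 3). Neither Btg2 nor any other measured member of the list passed the spread-adjusted rule. Matrix remodelling genes (median 0.39, percentile 92.26) stood higher with members of at least 500 mean reads only (0.71, percentile 99.42). Histone genes had a median of 1.17 over 30 members (16 higher, 3 lower, 11 neither; percentile 99.87), with H3f3b at 1.35 (0.732 to 2.57) and Hist1h2ap at 1.08 (0.424 to 2.83) times control. No member of the histone list passed the spread-adjusted rule. The ES library at 19 DIV also had the highest share of 0 counts among genes expected at 200 to 1000 reads, 9.09% against 4.78% to 6.17% in the other 3. With only members of at least 500 mean reads, a minimum added after seeing the data, histone genes (median 0.14 over 7, percentile 64.57), ion channels (-0.18 over 3, percentile 35.04) and fatty acid synthesis genes (-0.37 over 14, percentile 5.09) no longer stood apart. Against unmatched random lists the regeneration-associated and fatty acid synthesis genes did not, nor did the latter with members of at least 50 mean reads (median -0.47).

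Myelin genes did not stand apart at 19 DIV (median -0.25 over 24 members, 3 higher, 5 lower, 16 neither; percentile 7.74). With the 16 members of at least 500 mean reads the median was 0.38, on the other side of 0, and did not stand apart either (percentile 96.85). Mbp was at 0.674 (0.421 to 1.07), Pmp22 at 0.815 (0.492 to 1.35), Prx at 1.54 (0.771 to 3.22) and Mag at 2.11 (0.792 to 6.42) times control. Egr2 had 1935 reads in ES and 393 in control (4.25-fold, 0.780 to 54.9), and Sox10 and Ngfr were at 0.995 (0.534 to 1.87) and 0.911 (0.449 to 1.86). Oxidative stress genes did not differ as a list (median 0.16, percentile 73.58), with Mt1 at 1.05 (0.608 to 1.83) and Mt2 at 0.960 (0.502 to 1.85) times control. Immediate early genes had a median of 0.00 (percentile 52.93), with Fos at 0.993 (0.0828 to 13.6), Egr1 at 0.972 (0.226 to 4.34), Jun at 0.703 (0.211 to 2.24) and Atf3 at 2.45 times control (304 and 107 reads). The size rule gave 2945 genes higher and 3136 lower among 10027, 2294 of them with 0 reads in 1 library, and the spread-adjusted rule gave 13 and 13. Ulk2, Qars, Ogfod2, Daxx, Csrp2bp, Btg2, Hhip and Clcf1 had 1116 to 1651 reads in ES and 0 in control, at least 321-fold to at least 475-fold higher. Nrxn3, 9330159F19Rik, Ctnna2, Tagln3, Tcf7l1, Zdhhc2 and Abca8a had 919 to 1412 reads in control and 0 in ES, at least 355-fold to at least 545-fold lower. No gene with 0 reads in 1 library passed the spread-adjusted rule in this comparison. Ifi27, an interferon-stimulated gene, had 1 read in ES and 1385 in control (0.000623 times control, counting interval 1.58e-05 to 0.00348).

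**Figure D5:**
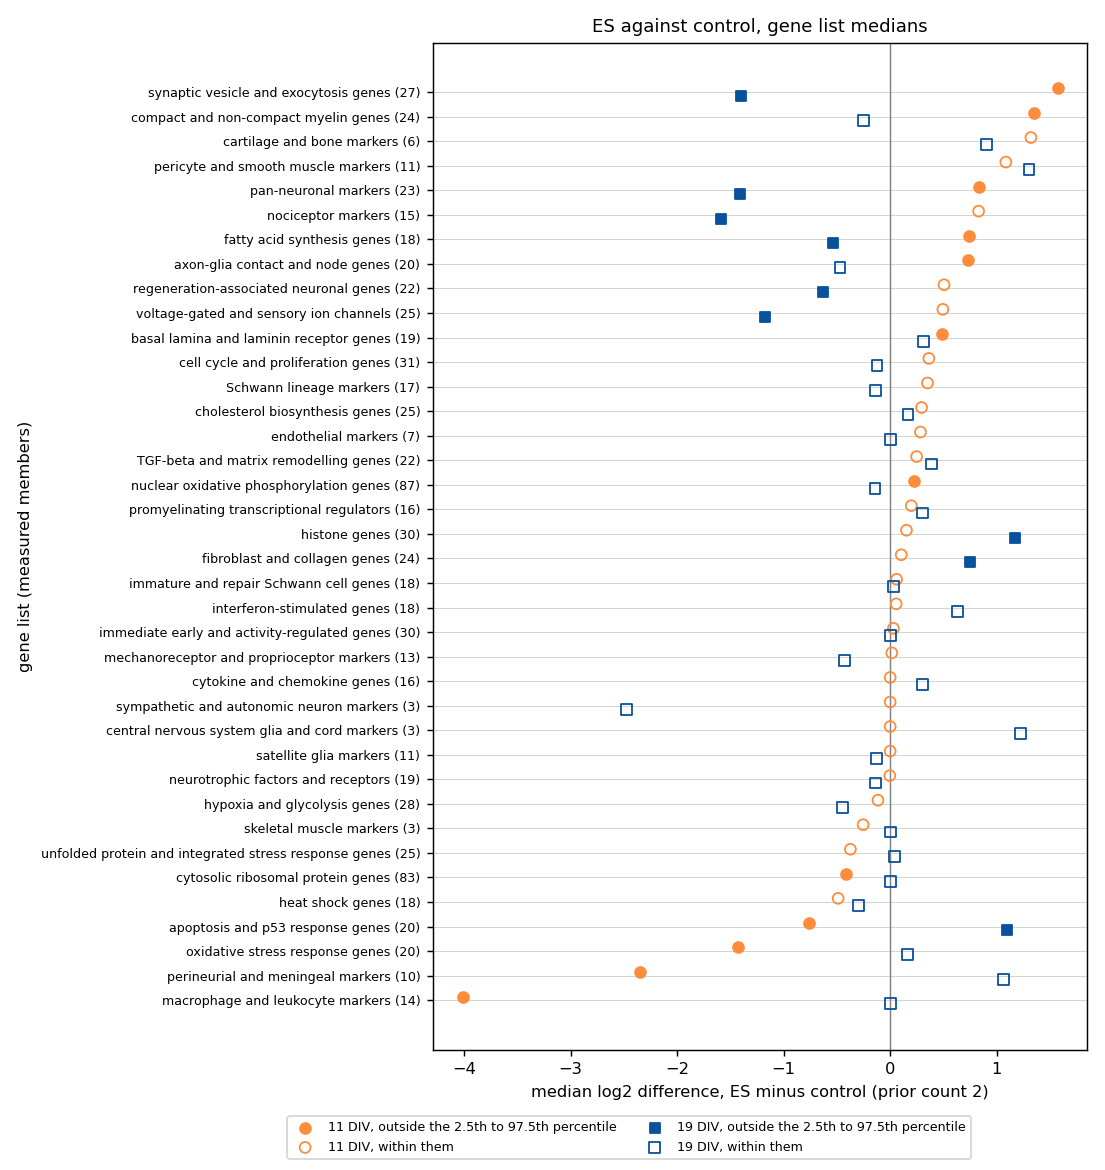
Median log2 difference between ES and control (horizontal axis) of the 38 gene lists with at least 3 measured members, at 11 DIV (circles) and 19 DIV (squares). Filled marks lie outside the central 95% of matched random lists, and pan-neuronal markers stood at 0.84 at 11 DIV and -1.41 at 19 DIV.

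Control cultures at 19 DIV were set against those at 11 DIV, 1 library each. Time without stimulation therefore cannot be told apart from differences between explant pools or libraries. Myelin genes were higher at 19 DIV. Their median log2 difference was 1.97 over 24 members (17 higher, 2 lower, 5 neither), at the 100th percentile. By the spread-adjusted rule 3 members were higher and 0 lower. Pmp22 was 3.78-fold (1.73 to 9.42), Prx 5.38-fold (1.31 to 41.8), Mbp 1.84-fold (1.08 to 3.25) and Mag 5.0-fold (0.659 to 177) higher. Pou3f1, a transcription factor of Schwann cells about to myelinate, was 3.88-fold higher (2.0 to 8.23), and Sox10 was at 1.01 (0.516 to 1.99). Egr2 had 393 reads against 3, a ratio of 110 with a counting interval of 37.4 to 536. Its spread-adjusted interval included equality. Synaptic vesicle genes (median 1.32, percentile 99.92), basal lamina genes (0.79, 99.93), axon-glia contact genes (0.94, 99.50), satellite glia markers (1.13, 98.78) and Schwann lineage markers (0.62, 97.65) were also higher. Syt4, a synaptotagmin, was 2.57-fold higher (1.05 to 7.20), Lama2, a laminin chain, 5.33-fold (1.16 to 52.3), and Col1a2 2.34-fold (1.70 to 3.27). Fibroblast and collagen genes (median 0.46, percentile 97.29), fatty acid synthesis genes (0.56, percentile 96.8) and ion channels (0.20, percentile 73.2) did not stand apart. They did, on the higher side, with members of at least 50 mean reads (0.50, 0.71 and 1.06) and of at least 500 (0.50, 0.57 and 2.02, the last over 3 members).

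Oxidative stress genes were lower at 19 than at 11 DIV in control, with a median of -1.92 over 20 members (0 higher, 12 lower, 8 neither; percentile 0). By the spread-adjusted rule 7 members were lower and 0 higher. Mt1 and Mt2 were at 0.106 (0.0686 to 0.159) and 0.0732 (0.0442 to 0.115) times their 11 DIV level, Prdx1 at 0.0861, and Hmox1 at 0.0288 (146 and 4258 reads). Gclm, an enzyme of glutathione synthesis, had 4 reads at 19 DIV and 2031 at 11 DIV. Ribosomal protein genes had a median of -0.73 over 83 members (1 higher, 22 lower, 60 neither; percentile 0), and Rps20 was at 0.433 (0.274 to 0.671). Apoptosis and p53 response genes (median -1.05, percentile 0.28; Cdkn1a at 0.292, 0.148 to 0.544) and hypoxia and glycolysis genes (-0.58, percentile 1.58) were lower. Rn45s was at 0.497 times its 11 DIV level (0.455 to 0.542). With 189732 reads at 19 DIV and 320992 at 11 DIV, it lay above the genes behind the spread factor. That interval may therefore be too narrow. At the added minimum of 500 mean reads, hypoxia and glycolysis genes (median -0.42, percentile 6.44), Schwann lineage markers (0.62, 97.1), satellite glia markers (0.86, 96.96) and axon-glia contact genes (0.72, 95.92) no longer stood apart, and against unmatched random lists the first 3 and the basal lamina genes did not. With members of at least 50 mean reads, Schwann lineage markers (median 0.55) did not. This comparison and that of ES with control at 11 DIV share the control library at 11 DIV, so their values are not independent. The size rule gave 3099 genes higher and 2992 lower among 10025, and the spread-adjusted rule 16 and 46. Snord49b, Rilpl2, Col15a1, Sorcs1, Bcl7a, Cdc37l1, Nfkb2 and Inmt had 1008 to 1264 reads at 19 DIV and 0 at 11 DIV, at least 282-fold to at least 354-fold higher. Ankra2, Ephx1, Aptx, Gab2, Tprkb, Angptl4, Gnb4 and Aldh3a1 had 751 to 1154 reads at 11 DIV and 0 at 19 DIV, at least 298-fold to at least 458-fold lower. No gene with 0 reads in 1 library passed the spread-adjusted rule between the days in control.

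Stimulated cultures were compared between the days in the same way, and fibroblast and collagen genes were higher at 19 than at 11 DIV, with a median of 1.33 over 24 members (15 higher, 1 lower, 8 neither), at the 100th percentile. Col1a1 was 2.09-fold (1.45 to 3.06), Col1a2 1.93-fold (1.46 to 2.57), Col5a2 3.95-fold (1.44 to 13.9) and Igfbp4 7.89-fold (2.74 to 32.8) higher. Matrix remodelling genes (median 0.74, percentile 98.68; Timp3 2.22-fold, 1.41 to 3.60), perineurial markers (3.40 over 10 low-count members, or 2.99 with members at 0 put at a count of 3; percentile 99.74), markers of the central nervous system (5.84 over 3 members, or 5.06; percentile 97.69) and myelin genes (0.52, or 0.44; percentile 97.67; 7 higher, 3 lower, 14 neither) also stood higher. Prx was 3.35-fold (1.24 to 11.3), Pou3f1 2.40-fold (1.15 to 5.47) and Mag 2.85-fold (0.866 to 12.8) higher, with Mbp at 0.895 (0.518 to 1.56). Pan-neuronal markers (median -1.11, percentile 0; 2 higher, 13 lower, 8 neither), synaptic vesicle genes (-1.44, percentile 0.015), regeneration-associated genes (-0.74, percentile 0.6), ion channels (-1.57, percentile 0.4), hypoxia and glycolysis genes (-0.72, percentile 0.3), ribosomal protein genes (-0.32, percentile 0.09), fatty acid synthesis genes (-0.57, percentile 1.76) and nuclear oxidative phosphorylation genes (-0.24, percentile 2.05) were lower. Tac1 was at 0.185 (0.0807 to 0.384), Prph at 0.285 (0.126 to 0.6) and Stmn2 at 0.311 (0.119 to 0.741) times the 11 DIV level. Oxidative stress genes had a median of -0.36 and did not stand apart (percentile 4.01), but did at the added minimum of 500 mean reads (-0.69 over 16, percentile 0.1), as did heat shock genes (-0.64 over 12, percentile 1.29, from -0.27 and percentile 14.75), and Prdx1 was at 0.313 (0.177 to 0.534). At that minimum the synaptic vesicle (median -0.27 over 11, percentile 22.3), ion channel (0.50 over 3, percentile 75.8), fatty acid (-0.40, percentile 5.95), oxidative phosphorylation (-0.12, percentile 8.44) and perineurial (0.98 over 3, percentile 85.7) lists no longer stood apart, and fewer than 3 central nervous system markers were left, as with a minimum of 50. Against unmatched random lists the regeneration-associated, myelin, fatty acid, hypoxia, matrix remodelling, ribosomal protein and oxidative phosphorylation lists did not stand apart, nor with members of at least 50 mean reads did the regeneration-associated (median -0.38), myelin (0.50), fatty acid (-0.43) and oxidative phosphorylation (-0.21) lists. The size rule gave 3052 genes higher and 3017 lower among 9884, and the spread-adjusted rule 16 and 26. Ccdc80, Mcts1, Osbpl1a, Adamts20, Mib2, Csrp2bp and Chid1 had 1277 to 2163 reads at 19 DIV and 0 at 11 DIV, at least 316-fold to at least 535-fold higher. Abca8a, Ncald, S100b, Nrxn3, Cadm3, Rnf103, Aagab and Syt7 had 819 to 1665 reads at 11 DIV and 0 at 19 DIV, at least 368-fold to at least 748-fold lower. Among all genes with 0 reads in 1 library, only 1 passed the spread-adjusted rule between the days in ES.

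The ES difference at 11 DIV and that at 19 DIV, which share no library, did not go together across genes. Over 9759 genes Pearson r was -0.033 and Spearman's rho -0.030, and 49.0% of the 9086 genes with a difference on both days had the same sign, where 50% is the chance level. Over 564 genes with a mean of at least 2000 reads, a minimum chosen after seeing the data, r was -0.042. The day difference in control and that in ES correlated with r = 0.003 over 9759 genes and r = 0.30 over the 564, in which 62.9% had the same sign. A model over all 4 libraries gave 0 genes for an ES effect common to both days and 0 for a day effect common to both treatments among 10050 tested (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p). At an unadjusted threshold of 0.05, 109 and 202 genes passed, fewer than the 5% of genes that chance alone gives. limma-voom also gave 0 for both, while DESeq2's Wald test gave 503 genes for ES (210 higher, 293 lower) and 832 for day (413 higher, 419 lower). In simulated clumped libraries the edgeR model recovered 1% of genes changed 2-fold by ES on both days and 40% of those changed 4-fold. The smallest edgeR p for ES, singled out after its values were seen, was that of Zwint, with 3309 and 997 reads at 11 DIV and 3282 and 593 at 19 DIV in control and ES (log2 difference -2.22, SE 0.485, adjusted p = 1). That for day was Gclm, with 2031 and 670 reads at 11 DIV and 4 and 3 at 19 DIV in control and ES (log2 difference -8.70, SE 1.0, adjusted p = 0.801).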

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

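The tests of explanations in this part were all chosen after the results had been seen, while the gene lists and their percentiles were planned. Several were altered or dropped after their values were seen. Tests that left the 50 most abundant genes out of the library sizes were dropped, because that moves every gene alike and leaves each list's percentile as it is. Sampling of few molecules has no test of its own, since the percentile of the myelin list is the pattern itself. The first test of the oxidative stress genes, the median of the less abundant 10 members, was -2.08 in ES at 11 DIV and -1.92 in control at 19 DIV, with 95% sign intervals reaching 0.24 and 0.11. It was replaced by the percentile without the 3 most abundant members, and then a sign interval below 0 was required as well. For the larger share of Schwann cells the bound was made stricter, and for the smaller share of neurons markers not already seen lower took the place of synaptic and nociceptor members.

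In the comparisons of ES with control, 4 gene lists stood apart on opposite sides at 11 and at 19 DIV, and with 1 library per group the difference was not tested. Synaptic vesicle and exocytosis genes had a median log2 difference of 1.57 at 11 DIV and -1.40 at 19 DIV. Pan-neuronal markers had 0.84 and -1.41, fatty acid synthesis genes 0.74 and -0.54, and apoptosis and p53 response genes -0.76 and 1.10. With only members of at least 500 mean reads, a minimum added after seeing the data, apoptosis and p53 response genes at 11 DIV (-0.61, percentile 6.37) and fatty acid synthesis genes at 19 DIV (-0.37, percentile 5.09) no longer stood apart. Nor did fatty acid synthesis genes on either day and apoptosis and p53 response genes at 11 DIV against unmatched random lists, or fatty acid synthesis genes at 19 DIV with members of at least 50 mean reads (-0.47, percentile 2.61).

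Neuronal genes were lower in ES than in control at 19 DIV. Loss of low-count genes in the ES library, which had the highest share of 0 counts, is argued against for pan-neuronal markers with a mean of at least 500 reads. The median of these 17 members was -1.41 (95% sign interval -1.59 to -0.55), at percentile 0 of random lists matched on mean reads. The sign intervals in this part treat genes of a list as independent, which they are not. For ion channels such a loss stays open, because only 3 members had at least 500 mean reads and their median was -0.18 (percentile 35.04). Stimulation and differences between explant pools stay open, as untested. A smaller share of neurons stays open too, because the interval of other neuronal markers was wide. The 9 mechanoreceptor and proprioceptor markers outside the lists that were lower had a median of 0.42, with a sign interval of -3.86 to 1.53. The reads of their whole list summed to 1.27 times control, with 1 member past the spread-adjusted rule higher and 0 lower. The median of that whole list was nevertheless -0.43 (percentile 16.8). Over its 6 members with at least 500 mean reads it was -0.64 (percentile 5.9). An equal gain of all other cells cannot be told apart from a gain of fibroblasts alone, because the sign intervals of the fibroblast list (0.35 to 1.11) and the Schwann lineage list (-0.34 to 0.69) overlapped, the first starting at -0.34 relative to the end of the second.

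Myelin genes were higher in ES than in control at 11 DIV. A larger share of Schwann cells cannot be told apart from higher myelin expression per cell, because the 12 Schwann lineage markers outside the myelin list had a median of 0.25 with a sign interval up to 0.83, which overlapped that of the myelin list (0.59 to 1.88). Over the whole Schwann lineage list, part of which is in the myelin list, the 13 members with at least 500 mean reads stood higher in ES (median 0.59, percentile 98.34). Stimulation and differences between explant pools both stay open, as untested. So does one unusual control library at 11 DIV, against which myelin genes were higher in control at 19 DIV too (median 1.97). In ES cultures, a comparison without that library, the myelin median at 19 against 11 DIV was 0.52 (percentile 97.67). It was 0.69 over members with at least 500 mean reads (percentile 99.78). With at least 50 it was 0.50 and did not stand apart (percentile 96.8), nor did the list against unmatched random lists.

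Oxidative stress genes were higher in control at 11 DIV than in the library each comparison set against it, and both comparisons share that control library. The 3 most abundant members, Mt1, Mt2 and Prdx1, were not the only ones lower. By the spread-adjusted rule 4 members were lower and 0 higher in ES at 11 DIV, and 7 and 0 in control at 19 DIV. Without those 3 the list had a percentile of at most 0.01 in both comparisons. Whether a few abundant members carried the whole pattern stays open. The sign intervals of the medians of the other 17 members (-1.27 and -1.65) reached 0.04. One unusual culture or library cannot be told apart from a state of unstimulated ganglia at 11 DIV, since that group had 1 library. In ES cultures, a comparison without that library, the list's reads at 19 DIV summed to 0.647 times those at 11 DIV, and its median was -0.36 (percentile 4.01), or -0.69 (percentile 0.1) over members with at least 500 mean reads.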

How the results depend on the processing

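The settings named below as added were chosen after seeing the data, and the others were planned. No replicate could be left out, since each group had 1 library and an additive fit to 3 libraries has no residual degrees of freedom. No paired analysis was possible because the groups shared fewer than 2 replicate numbers. The model over 4 libraries took day as a block for ES and ES as a block for day, and without the other factor edgeR gave 0 genes as well (250 for ES and 490 for day at an unadjusted p under 0.05). Every count of genes by the size rule stayed within 1.5 times under DESeq2 size factors, plain library size, library size without the 50 most abundant genes, a count minimum of 20 or none, fold minimums of 1.5 or 3 and thinning to the smallest total. Plain library size shifted every gene in both comparisons with control at 11 DIV by 0.13 on the log2 scale and reversed no median of a list standing apart and no named gene past the size rule. It moved 159 gene values beyond their counting intervals, and DESeq2 size factors moved 9.

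With a count minimum of 200, genes higher and lower numbered 1739 and 1769 for ES at 11 DIV, and genes lower numbered 2049 for ES at 19 DIV, 1818 for day in control and 1843 for day in ES. An added minimum of 2000 reads gave 49 higher and 73 lower for ES at 11 DIV, 116 and 68 at 19 DIV, 100 and 110 for day in control, and 138 and 66 for day in ES. Both drop because fewer genes are counted. The added spread-adjusted interval gave, in the same order, 10 and 21, 13 and 13, 16 and 46, and 16 and 26. Its first version gave 4 and 8, 3 and 1, 9 and 24, and 10 and 15. Both drop because the intervals are wider.

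Against unmatched random lists, 3 lists stood higher for ES at 11 DIV, and 3 higher and 3 lower for day in ES. In the 4 comparisons 7 of 12, 7 of 9, 6 of 10 and 6 of 13 lists kept their side, and 2 others came to stand apart for day in control. Members with at least 50 mean reads gave 3 higher and 5 lower for day in ES, and 10 of 12, 8 of 9, 9 of 10 and 8 of 13 lists standing apart in the 4 comparisons kept their side, while 2, 1, 3 and 0 others came to stand apart. With an added minimum of 500 mean reads, 2 stood lower for ES at 11 DIV and 3 higher for day in ES, and the medians of perineurial markers for ES at 11 DIV and of ion channels for day in ES reversed to 0.82 and 0.50. Of the medians of lists not standing apart, 5 also changed sign under plain library size, 2 at 50 mean reads and 14 at 500, among the 14 those of myelin (0.38), interferon-stimulated (-0.14) and neurotrophic genes (0.25) for ES at 19 DIV. The cause was not tested for these lists. At 500 reads, 9 of 12, 6 of 9, 6 of 10 and 7 of 13 lists standing apart in the 4 comparisons kept their side, and 1, 2, 3 and 2 others came to stand apart. With members at 0 reads put at a count of 3, medians of lists standing apart that are not given so above shifted by at most 0.042. DESeq2's Wald test gave 503 genes for ES and 832 for day against 0 from edgeR (109 and 202 at an unadjusted p under 0.05) and 0 from limma-voom, and the cause was not tested. Pearson's r of the ES differences on the 2 days stayed between -0.042 and -0.023.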

Other observations

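The genes singled out in this part were chosen after their values were seen. Cyb5r3, a cytochrome b5 reductase, was at 0.491 times control in ES at 11 DIV (5242 and 10445 reads) and 2.05-fold higher in ES at 19 DIV (19868 and 8375 reads), past the spread-adjusted rule on both days. Nrxn2 and Tac1 lay on the other side, higher in ES at 11 DIV and lower at 19 DIV, also past that rule on both days. The difference between the days was not tested for these 3 genes.

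The following lists of other cell types did not stand apart in ES against control on either day, unlike fibroblast, macrophage and perineurial markers. With members of at least 50 mean reads, however, Schwann lineage markers stood higher at 11 DIV (median 0.47 over 16, percentile 97.66), as they did at an added minimum of 500 (0.59 over 13, percentile 98.34). At 50 mean reads cartilage and bone markers did so too (median 2.64 over 5, percentile 98.33). The medians at 11 and 19 DIV were 0.35 and -0.13 for Schwann lineage markers, 0.06 and 0.03 for immature and repair Schwann cell genes, 0.00 and -0.12 for satellite glia, 0.28 and 0.00 for endothelial cells, 1.09 and 1.30 for pericytes and smooth muscle, 1.32 and 0.90 for cartilage and bone, -0.25 and 0.00 for skeletal muscle, and 0.00 and -2.48 for 3 sympathetic neuron markers. Nor did promyelinating transcription factors (0.20 and 0.31), neurotrophic factors and receptors (0.00 and -0.13), cell cycle genes (0.36 and -0.12), cholesterol biosynthesis genes (0.30 and 0.17), heat shock genes (-0.49 and -0.30), unfolded protein response genes (-0.37 and 0.04), interferon-stimulated genes (0.06 and 0.63) or cytokine genes (0.00 and 0.30).

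Akap5 and Lrrc17, which are not related genes, had nearly identical counts, 52835 and 53058 reads in control at 11 DIV, 61142 and 62323 in ES at 11 DIV, 25555 and 25267 in control at 19 DIV, and 27830 and 28289 in ES at 19 DIV. Both rows were lower at 19 DIV, at 0.406 and 0.40 times in control and at 0.338 and 0.337 times in ES, and passed the spread-adjusted rule. Reads counted for both genes at once would look the same. These folds and calls are therefore uncertain for either gene.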
